A study of Mus musculus with 4 samples.

How the data were processed

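RNA from the E14 line of mouse embryonic stem cells was profiled on 4 Illumina bead arrays labelled with Cy3, a single colour. Per the labels, the cells were grown in serum medium with LIF and were exposed for 2 hours to ATRA (all-trans retinoic acid) or to DMSO, its vehicle, with 2 arrays per group. The treatment field names the vehicle for the control arrays, while the source name and the series design call the same arrays untreated; the groups were taken from the treatment field. The ATRA concentration is not given in the sources used here.

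Per the submitters' processing notes, the values came from GenomeStudio; no version is given in the sources used here, nor any further step. The authors deposited a table of intensity values on a linear scale with, per the file headers, a detection p-value beside each value. That table is named as non-normalized, but its sorted intensities were the same on the 4 arrays to within 0.228, so the deposited intensities were already quantile normalized between arrays. They were not background-subtracted, with a lowest value of 78.1. The deposited series matrix holds the same intensities minus a constant of 93.5 on every array, to within 0.0062. It is therefore linear and not centred per probe, with medians of 6.22 to 6.24 and 30.1% to 30.2% of values below 0. The files name no chip or scan.

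The main values were made from the table with detection p-values, using limma 3.58.1 in R 4.3.3. The neqc function corrected the background by normexp, with the negative controls inferred from the detection p-values, added an offset of 16, quantile normalized the arrays and took log2. Because the deposited values were already quantile normalized, this second quantile step had little left to change, and a shift common to most probes could not be measured. Fold changes are on the log2(value + offset) scale, so they understate the change of dim probes. Probes were kept when their detection p was under 0.05 on at least 2 of the 4 arrays, whatever the group. This kept 19112 of 45281 probes (42.2%).

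Probes were named from the platform annotation given with the series: 34885 had 1 symbol, 18 had several and 10378 were unnamed here. Of those with 1 symbol, 34807 were matched through their Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, none of which changed its symbol (0 renamed), and 78 kept the annotation's symbol. Kept probes with 1 symbol numbered 15993 and covered 10194 genes. A gene with several kept probes was represented by the probe with the highest mean over the 4 arrays. For named genes and genes past the threshold, another kept probe that differed in direction or in passing the threshold is stated beside the gene or counted. Genes that passed only by a dimmer probe enter a count of symbols and are not listed. No genome build is named in the files, so no coordinates are given.

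ATRA was compared with DMSO by lmFit and eBayes with an intensity trend, with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all kept probes at a threshold of 0.05. Errors of changes are limma's standard errors, and intervals are 95% confidence intervals from the same fit; group values are mean log2 intensities ± SD over 2 arrays. All adjusted p-values of single genes come from this limma test unless another is named. The 4 arrays limit the precision. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 2 arrays against 2, an exact permutation test of a single gene cannot give a p under 0.333, so none was used for single genes. For a probe undetected on both arrays of a group, the change is given as a bound: the mean of the brighter group against, on each dim array, the higher of the probe's own value and the lowest value among detected probes. The bound carries no sampling error, so the interval of the fit can reach below it.

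The fit was tested on simulated data with the means of the same 19112 probes and with noise drawn from the fit's own variance model. That noise was normal, equal in both groups and independent between probes. The counts that follow therefore hold only for such data, and do not test departures from that model. Of 100 probes raised or lowered by 0.5 on the log2 scale it recovered 47, and of 100 changed by 1 it recovered 97, with 4 false calls among 148. In the simulated lists, camera with its preset correlation called a list of 15 genes with 8 members raised by 0.5. It called 0 of 28 unchanged lists. With an estimated correlation the raised list was not called, so a miss in that form decides little.

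The comparison, the filter, the threshold, the 30 gene lists, the naming rule and the main alternatives were fixed before the data were examined. The named genes are the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, 16 genes chosen in advance, and up to 4 members past the threshold of each list. These made 47 genes, and 6 of the 16 had no kept probe. An item among those chosen in advance is not reported here. The lists were tested by camera with a preset correlation of 0.01, two-sided, where at least 5 genes were measured, with Benjamini-Hochberg adjustment over the 28 lists tested. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance, and its mixed form tests for change in either direction; neither compares the list with other genes. Of 655 list entries, 30 were matched by an older symbol and 3 were unmatched or dropped. The dropped entry, Gp130, had matched an unrelated gene by a synonym. It was removed after the list results had been seen, and the LIF and STAT3 list was past the threshold neither with it nor without it.

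The alternatives tried were no background correction, median centring in place of quantile normalization, an offset of 50, no filter on dim probes, detection p under 0.01 on all 4 arrays, the series matrix values, eBayes without the intensity trend, a replicate block, the mean of all probes of a gene, and leaving out each array in turn. A robust eBayes and the retinoic acid responsive list without Cyp26a1 and Cdx1 were added after the data had been seen.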

Results

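Gene expression was measured in E14 mouse embryonic stem cells, an established line kept in serum and LIF, 2 hours after addition of the vehicle DMSO or of ATRA, the ligand of the retinoic acid receptors. There were 2 arrays per group, each with 45281 probes. The deposited intensities ran from 78.1 to 26003 on every array, with medians of 99.7 to 99.8. Of the probes, 42.3% and 41.2% were detected on the DMSO arrays and 40.1% and 41.8% on the ATRA arrays (detection p under 0.05), and the detection limit lay at an intensity of 104.4 to 106.3. Over the kept probes, the log2 values of replicates correlated across probes with r = 0.9944 for DMSO and 0.9963 for ATRA, against 0.9933 to 0.9941 between arrays of different groups; probes are not independent replicates. The median SD between replicates was 0.093 for DMSO and 0.072 for ATRA on the log2 scale. The series title places the arrays in a study of retinoic acid made by embryonic stem cells and of their differentiation, and the comparison asks which transcripts differ shortly after added ATRA.

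With ATRA, Cyp26a1, which encodes an enzyme that degrades retinoic acid, rose 3.97-fold (95% interval 3.25 to 4.84), from 4.92 ± 0.20 to 6.91 ± 0.11 (mean log2 intensity ± SD, n = 2; limma adjusted p = 2.6e-09). Otx2, a homeodomain transcription factor of the epiblast and anterior neural tissue, fell from 8.75 ± 0.06 to 6.92 ± 0.11 (n = 2), and was 3.55 times lower (adjusted p = 4.4e-11). In all, 302 of 19112 probes passed the threshold, of which 240 rose and 62 fell. With each gene given by its brightest probe, 149 genes rose and 37 fell among 10194. By any kept probe 222 symbols passed, which is more because some genes passed only by a dimmer probe. Most changes were small: 22 probes rose and 1 fell by 2-fold or more, 117 rose and 15 fell by 1.5-fold or more, and the median change of all kept probes was -0.007 on the log2 scale. On all 302 probes both ATRA arrays lay beyond both DMSO arrays, as they did on 40.8% of all kept probes, against 33.3% by chance.

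Aqp3, a water and glycerol channel, rose from 7.06 ± 0.18 to 8.68 ± 0.04 (n = 2), by 3.08-fold (SE 0.10 on the log2 scale, adjusted p = 5.7e-10). Camk2n1, an inhibitor of the kinase CaMKII, rose 2.61-fold (adjusted p = 6.9e-09), with its other probe higher by 1.31 on the log2 scale (adjusted p = 1.1e-08). Spsb1, a SOCS box adaptor of ubiquitin ligases, rose 2.45-fold (adjusted p = 6.9e-09), and the peptide hormone gene Edn2 rose 2.40-fold (adjusted p = 3.3e-05). Dleu7 and the TGF-beta binding protein gene Ltbp3 rose 2.39-fold and 2.29-fold. Edn2 and Dleu7 were detected on 1 of the 2 DMSO arrays, so their folds are set against values near background. Aurkc, the germline Aurora kinase, rose 2.36-fold (adjusted p = 6.1e-08), while its other probe was higher by 0.67 and missed the threshold (adjusted p = 0.051). Tmem191c rose 2.32-fold by its brightest probe, while its other probe was higher by 0.42 (adjusted p = 0.30). H2-Bl rose 2.19-fold; it belongs to the class I histocompatibility family, whose members are similar in sequence, so that the source of its signal is uncertain. The sizes and order of these rises depended on the background correction. Without it Cyp26a1, Edn2, Dleu7, Ltbp3 and H2-Bl were 1.73-fold, 1.33-fold, 1.32-fold, 1.36-fold and 1.43-fold higher and Aqp3 was 2.22-fold higher. With an offset of 50 Cyp26a1 was 2.40-fold and Aqp3 2.65-fold higher, so Cyp26a1 was below Aqp3 in both.

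After Otx2, the largest fall by brightest probe was that of Id2. This inhibitor of basic helix-loop-helix factors fell by 0.91 on the log2 scale (SE 0.11, adjusted p = 1.5e-05), while its other probes were lower by 0.29 and 0.47 without passing (changes of -0.29 and -0.47, adjusted p = 0.59 and 0.11). Sox21, a relative of Sox2, fell by 0.73 (adjusted p = 0.00043). The homeobox gene Evx1 fell by 0.66 (adjusted p = 0.024) and Sp5, a zinc finger factor induced by WNT, fell by 0.64 (adjusted p = 0.012). Zbtb46 was detected on both DMSO arrays and on 0 of the ATRA arrays, at least 1.38-fold lower (adjusted p = 0.042). The pseudogene Pisd-ps2 fell by 0.64, Rnd3 by 0.60, the receptor gene Gpr83 by 0.58 and the vesicular nucleotide transporter gene Slc17a9 by 0.57 (adjusted p = 0.0036, 0.023, 0.010 and 0.0040). The other probe of Slc17a9 changed by -0.42 without passing (adjusted p = 0.11), and a pseudogene probe can also read its parent gene. The falls too were smaller with no background correction, and their order changed. Evx1, Sp5, Zbtb46 and Rnd3 were then at -0.20, -0.23, -0.20 and -0.21.

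The calls rested on 2 arrays a group. Without ATRA replicate 1 the number of probes past the threshold was 133, without ATRA replicate 2 it was 147, and without DMSO replicates 1 and 2 it was 495 and 956. With eBayes run without the intensity trend it was 74, with 70 rises and 4 falls. Among the 10 largest rises and 10 largest falls, Zbtb46, Evx1, Sp5, Rnd3, Gpr83 and Slc17a9 no longer passed without ATRA replicate 1. Their changes were then -0.65, -0.56, -0.67, -0.59, -0.53 and -0.56. Zbtb46, Sp5 and Rnd3 did not pass without ATRA replicate 2 either, with changes of -0.74, -0.61 and -0.62. Zbtb46 was not kept when DMSO replicate 1 or 2 was left out. The 6 genes named first and Pisd-ps2 also missed the threshold without the trend, while Otx2, Id2, Sox21 and the 10 largest rises passed under each of these settings.

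**Figure D1:**
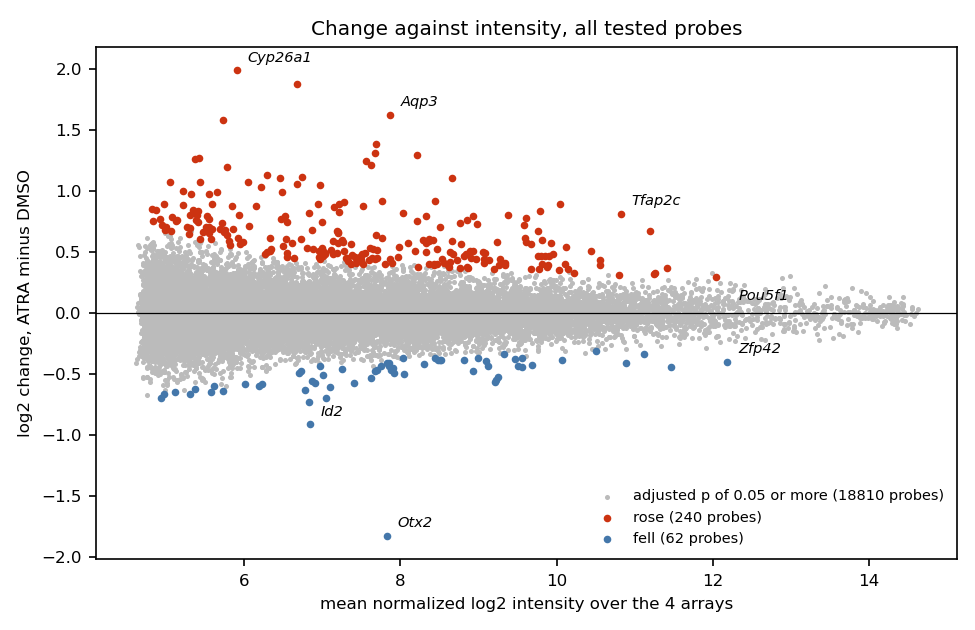
Change in log2 intensity from DMSO to ATRA (y axis) against the mean log2 intensity over the 4 arrays (x axis) for each of the 19112 kept probes, with probes past the threshold coloured by direction. Coloured points above 0 (240) outnumber those below (62), with Cyp26a1 the highest of the named genes and Otx2 the lowest.

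Genes known to respond to retinoic acid stood higher as a group. Of the 20 measured members of the retinoic acid responsive list, 18 were higher with ATRA, with a median change of 0.34 on the log2 scale, and 4 rose and 1 fell past the threshold; 11 passed when adjusted over the list alone (9 higher, 2 lower). Besides Cyp26a1, the risers were Cdx1, a caudal homeobox gene with a retinoic acid response element (1.83-fold, adjusted p = 0.00083; its other probe 1.58 on the log2 scale), the basic helix-loop-helix repressor Bhlhe40 (1.56-fold, adjusted p = 0.00048) and Skil (1.31-fold, adjusted p = 0.016), a SMAD co-repressor. Tgif1, another co-repressor of SMAD and retinoid signalling, fell by 0.39 (adjusted p = 0.022), and the other probe of Skil and the other probes of Tgif1 missed the threshold. The list was called by camera (adjusted p = 3.3e-08) and by fry (adjusted p = 0.045), and had an adjusted p = 0.61 with an estimated correlation. The simulated list with raised members was not called in that form either.

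The retinoid receptor list had 12 measured members, and 0 rose or fell. Rarb, a direct target and receptor of retinoic acid, was undetected on both DMSO arrays and detected on both ATRA arrays, at least 1.10-fold higher, and did not pass (adjusted p = 0.19). Rara was higher by 0.43 (adjusted p = 0.15). In the retinoid metabolism and transport list Cyp26a1 rose and the other 10 measured genes did not pass, among them Crabp2, a retinoic acid carrier, at 0.15 (adjusted p = 0.76). The camera adjusted p was 0.35 for each of these lists. When adjusted over the list alone, 2 receptor genes and 1 metabolism gene passed. The metabolism list was not tested without Cyp26a1, whose change of 1.99 stood beside a list median of 0.015. Stra6, Dhrs3, Aldh1a2 and Rdh10, genes of retinoid uptake and metabolism, were detected on 0 of the 4 arrays by every probe named for them. Without DMSO replicate 2 the number of responsive genes past the threshold was 8 and without ATRA replicate 1 it was 3, and the receptor list had 1 gene past the threshold without DMSO replicate 1 and 1 without DMSO replicate 2; without the intensity trend the responsive list had 1, as Cdx1, Bhlhe40, Skil and Tgif1 missed it (adjusted p = 0.090, 0.064, 0.23 and 0.25). Skil and Tgif1 had an adjusted p of 0.47 and 0.25 without ATRA replicate 1, Tgif1 of 0.16 without ATRA replicate 2 and 0.066 without DMSO replicate 1; the metabolism list had a camera adjusted p of 0.013 without DMSO replicate 1 and 0.031 without ATRA replicate 2.

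Hox genes, which pattern the body axis and whose anterior members respond to retinoic acid, were near or below the detection limit. Of 14 genes of paralog groups 1 to 5 on the array, 6 were detected on no array and 4 were kept. Hoxa5 and Hoxb5 were undetected on both DMSO arrays and at least 1.26-fold and 1.17-fold higher with ATRA, and Hoxb4 and Hoxb2 had changes of 0.47 and 0.36 (adjusted p = 0.12 to 0.43 for the 4 genes). None passed over all probes (0 of 4), and 3 passed when adjusted over the list alone. Too few were kept for the list test; with no filter on dim probes, the 14 genes stood higher (camera adjusted p = 0.029), with an adjusted p = 0.63 with an estimated correlation. Hoxb1 was detected on 0 of the 4 arrays. Of 24 genes of groups 6 to 13, 10 were kept, 0 rose or fell, 1 passed over the list alone, and the median change was 0.02 (camera adjusted p = 0.71; fry adjusted p = 0.045, higher). Without DMSO replicate 2, 1 gene of paralog groups 1 to 5 passed over all probes, and the list of Hox cofactors and Cdx genes had 1 past the threshold without DMSO replicate 1, ATRA replicate 1 or ATRA replicate 2. Among the 11 measured Hox cofactors and Cdx genes, Cdx1 rose and Tgif1 fell, 3 passed over the list alone, and Cdx2 was at 0.30 (adjusted p = 0.33; list camera adjusted p = 0.35).

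Most of the 34 measured pluripotency genes did not pass: 1 rose and 3 fell. When adjusted over the list alone, 7 passed (2 higher, 5 lower). The share that passed over all probes was still larger than that of all measured genes (186 of 10194). Fry's mixed test for change in either direction gave the list an adjusted p of 0.018. Pou5f1 changed little in value, from 12.19 ± 0.13 to 12.22 ± 0.04 (n = 2; 1.02-fold, 95% interval 0.915 to 1.15, adjusted p = 0.93), and Nanog was at 0.20 (95% interval 0.05 to 0.36, adjusted p = 0.25). Zfp42, a marker of the naive state, fell by 0.40 (adjusted p = 0.0041), Sox2 by 0.39 (adjusted p = 0.019) and Klf5 by 0.34 (adjusted p = 0.041), while Dppa2, a chromatin factor of pluripotent cells, rose 1.67-fold (adjusted p = 1.7e-05). The other probe of Sox2 was at -0.23 and missed the threshold (adjusted p = 0.51). The list's median was 0.03 and its mean -0.011, with camera pointing down (adjusted p = 0.62). Dppa2 passed with any array left out. Sox2 and Zfp42 had an adjusted p of 0.22 and 0.15 without ATRA replicate 1, Sox2 of 0.23 without ATRA replicate 2, and Klf5 of 0.13 and 0.58 without DMSO replicate 1 and ATRA replicate 1; without DMSO replicate 2 and ATRA replicate 1 the list had 8 and 1 members past the threshold. Without the intensity trend Sox2, Zfp42 and Klf5 missed the threshold (adjusted p = 0.20, 0.21 and 0.36) and Dppa2 did not.

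Genes of the primed epiblast, the state that follows naive pluripotency, were represented by 8 measured members, of which Otx2 fell and Wnt8a rose. Wnt8a, a WNT ligand, was undetected on both DMSO arrays and at least 1.43-fold higher with ATRA (adjusted p = 0.039; its other probe 0.84 on the log2 scale, adjusted p = 0.011). No other member passed over all probes, 2 passed when adjusted over the list alone, and Pou3f1 and Zic2 were at -0.18 and -0.15 (the other Zic2 probe 0.31, adjusted p = 0.47). No list test was run without Otx2, whose change of -1.83 stood beside a list median of -0.13. The list results may thus rest on that gene. The list had a camera adjusted p of 0.24, an adjusted p = 0.63 with an estimated correlation, and a fry adjusted p of 0.045, lower. Its camera adjusted p was 0.0033 and 0.018 without DMSO replicates 1 and 2, and 3.1e-05 and 4.7e-06 without ATRA replicates 1 and 2; Wnt8a had an adjusted p of 0.082 without DMSO replicate 2 and 0.11 without the intensity trend, and was not kept when ATRA replicate 1 or 2 was left out.

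Among lineage regulators, Gata6, a factor of primitive endoderm, rose 1.68-fold (95% interval 1.30 to 2.17, adjusted p = 0.027). It was detected on 1 of the 2 DMSO arrays, so this fold is set against a value near background. Tfap2c, a factor of trophectoderm and germ cells, rose 1.76-fold (adjusted p = 5.6e-07), and its 2 other probes rose too. Of the 6 measured streak and mesoderm genes, Lefty1, a NODAL inhibitor, rose 1.49-fold (adjusted p = 0.00043), Nodal rose 1.28-fold (adjusted p = 0.021; its other probe 0.29, adjusted p = 0.16) and Evx1 fell; 5 passed when adjusted over the list alone, and the camera adjusted p was 0.11. Gata6 was the only member of the 11 endoderm genes and Tfap2c the only member of the 9 trophectoderm genes to pass, with camera adjusted p of 0.62 for each and 1 and 3 members passing over the list alone. The 11 early neural genes gave 0 calls over all probes and 4 over the list alone (camera adjusted p = 0.86). The 7 germline genes gave 0 in both, as did the 12 genes of the 2-cell-like state (camera adjusted p = 0.62 and 0.35). Fry's mixed test gave adjusted p of 0.026, 0.016 and 0.04 for the streak, trophectoderm and early neural lists. For the endoderm, germline and 2-cell-like lists it gave 0.21, 0.81 and 0.58. Zscan4c, a marker of that state from a family of similar genes, was at 0.17 (adjusted p = 0.53), with its other probe at -0.13. Without ATRA replicate 1, Gata6, Nodal and Evx1 had adjusted p of 0.62, 0.34 and 0.34; Gata6 had 0.082 without DMSO replicate 1, Nodal 0.16 without ATRA replicate 2, Zscan4c passed without DMSO replicate 2 (adjusted p = 0.039), and the streak list had a camera adjusted p of 0.011 without DMSO replicate 1. Without the intensity trend Gata6, Lefty1 and Nodal missed the threshold (adjusted p = 0.15, 0.11 and 0.26) and Tfap2c did not. The early neural list had 1 member past the threshold without DMSO replicate 1 and 3 without DMSO replicate 2, the 2-cell-like list had 2 without DMSO replicate 2, the streak list had 1 without ATRA replicate 1, and the endoderm list had 0 without DMSO replicate 1 or ATRA replicate 1.

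**Figure D2:**
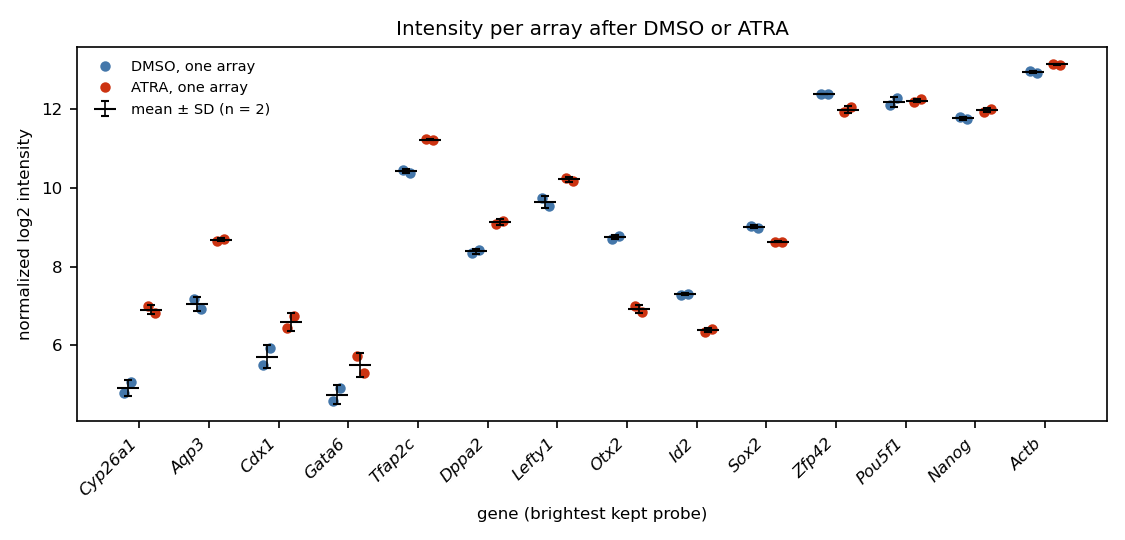
Log2 intensity of named genes on each array (points, 2 DMSO and 2 ATRA arrays per gene; bars, group mean ± SD). Cyp26a1 and Aqp3 are higher and Otx2 is lower on both ATRA arrays, while Pou5f1 overlaps between the groups.

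Components and targets of signalling pathways changed in both directions. Camera looks for a shift in 1 direction. Fry's mixed test, for change in either direction, gave adjusted p of 0.016, 0.0076 and 0.0076 for the BMP, WNT and LIF lists. It called 17 of the 28 lists tested and compares no list with other genes. Over all measured genes, 186 of 10194 passed. Of 12 measured BMP and TGF-beta target genes, Lefty1, Nodal and Skil rose and Id2 and Tgif1 fell, and 6 passed when adjusted over the list alone (camera adjusted p = 0.71); the mean change was -0.003 and the median 0.02, camera pointing up and fry down. Of 11 WNT target genes, Cdx1, Wnt8a and the receptor gene Fzd7 (1.41-fold, adjusted p = 0.0025) rose and Sp5 fell, and 7 passed over the list alone (camera adjusted p = 0.30). Axin2, a feedback inhibitor of WNT signalling, was at -0.39 (adjusted p = 0.081). Of 17 LIF and STAT3 target genes, the kinase gene Pim1 rose 1.85-fold (adjusted p = 0.0052). Pim1 was detected on 1 of the 2 DMSO arrays, so this fold is set against a value near background. Its rise was 1.2-fold with no background correction. Socs2, a feedback inhibitor of cytokine signalling, fell by 0.41 (adjusted p = 0.0042), as did Klf5 by 0.34. Over the list alone 5 passed, and the list had a camera adjusted p of 0.11. Without ATRA replicate 1, Fzd7 and Socs2 had adjusted p of 0.063 and 0.085; without ATRA replicate 2, Pim1 had 0.26 and the LIF list had a camera adjusted p of 0.037. Without the intensity trend Fzd7, Pim1 and Socs2 missed the threshold (adjusted p = 0.14, 0.090 and 0.18), as did Lefty1, Nodal, Skil, Tgif1, Cdx1, Wnt8a, Sp5 and Klf5. The LIF list had 5 members past the threshold without DMSO replicate 2 and 1 without ATRA replicate 1; without ATRA replicates 1 and 2 the BMP list had 2 and 3, and the WNT list 1 and 2.

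Dusp5, a phosphatase that inactivates ERK, rose 1.83-fold (adjusted p = 1.6e-05) and Gadd45b, a stress and growth arrest gene, rose 1.74-fold (adjusted p = 0.0042; its other probe 0.21, adjusted p = 0.71). They were the only 2 of 17 measured immediate-early genes to pass; Fos, Egr1 and Jun were at 0.06, 0.20 and 0.01 (list camera adjusted p = 0.35, 4 over the list alone). Dusp5 was the only one of 16 FGF and ERK feedback genes to pass, with Spry4 at -0.11 and Dusp6 at 0.10, its 2 other probes at -0.09 and -0.05 (camera adjusted p = 0.62, 4 over the list alone). Of 23 heat shock and unfolded protein genes, Ddit3, a stress transcription factor, rose 1.51-fold (adjusted p = 0.0027), with its other probe also past the threshold (camera adjusted p = 0.35, 4 over the list alone). Of 16 p53 target and apoptosis genes, Sesn1, a stress-response inhibitor of mTORC1, rose 1.45-fold (adjusted p = 0.0075) and Bcl2l11, a pro-apoptotic BCL2 relative, rose 1.42-fold (adjusted p = 0.0083; 2 other probes missed the threshold), while Cdkn1a was at -0.07, its 2 other probes at -0.12 and 0.11 (camera adjusted p = 0.35, 3 over the list alone). Without ATRA replicate 1, Ddit3 and Sesn1 had adjusted p of 0.16 and 0.14; without ATRA replicate 2, Bcl2l11 had 0.23. Without the intensity trend Gadd45b, Ddit3, Sesn1 and Bcl2l11 missed the threshold (adjusted p = 0.14, 0.096, 0.16 and 0.12) and Dusp5 did not. Without DMSO replicate 2 the p53, heat shock and FGF lists had 5, 3 and 2 members past the threshold; the p53 list had 1 without either ATRA replicate, and the heat shock list had 0 without ATRA replicate 1.

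The remaining lists gave no gene past the threshold over all probes. They were Notch targets (8 measured, 2 over the list alone, camera adjusted p = 0.87), oxidative and xenobiotic response (13, 0 and 0.62), sterol biosynthesis (17, 0 and 0.45), cell cycle (18, 0 and 0.69), imprinted genes (14, 1 and 0.35), histone genes (16, 0 and 0.62) and housekeeping genes (14, 0 and 0.62). The housekeeping median was -0.025. Actb was at 0.20 by its brightest probe (adjusted p = 0.23), and its 4 other probes were at -0.35 to -0.06, so that the mean of its probes was -0.16. Markers of embryonic fibroblasts, which serve as feeder cells in some embryonic stem cell cultures, had a median of -0.087 over 13 genes. Of these markers 0 passed the threshold, and the list's camera adjusted p was 0.29. Their mean deviation was 0.046 and 0.036 on the DMSO arrays and 0.027 and -0.11 on the ATRA arrays, and without ATRA replicate 1 their camera adjusted p was 0.038. The counts of 0 moved with an array left out: 1 gene each of the Notch, oxidative, sterol, imprinted and fibroblast lists passed without DMSO replicate 1, and 1 each of the Notch, imprinted and cell cycle lists without DMSO replicate 2. Of the hematopoietic and endothelial markers 4 were measured, with 0 past the threshold and too few for the list test.

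**Figure D3:**
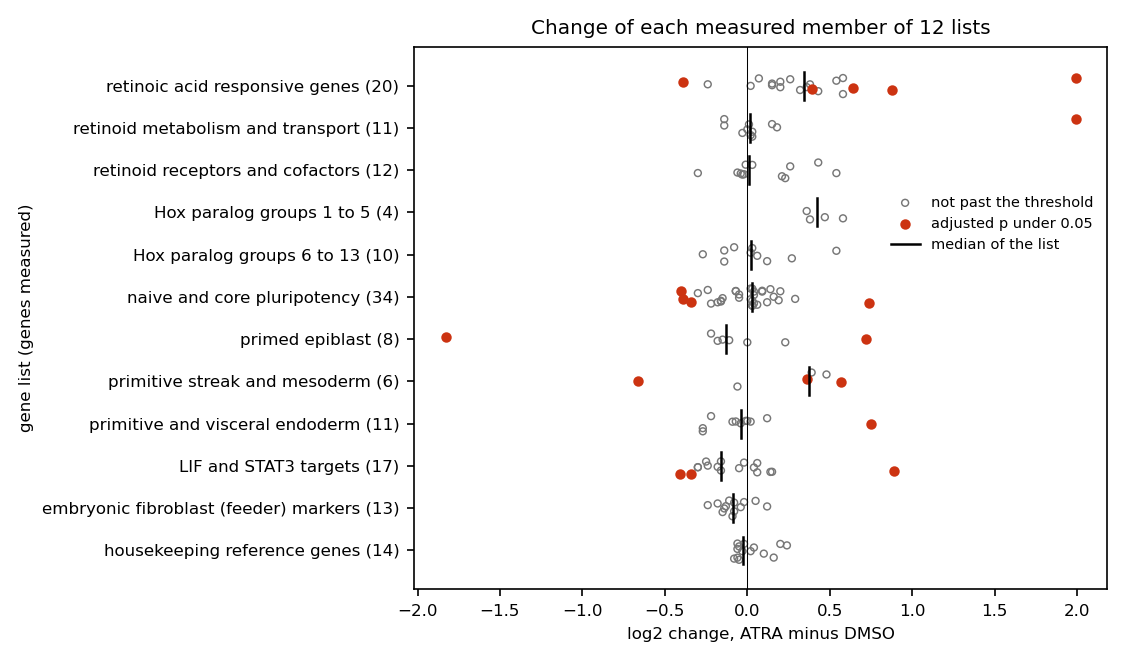
Change in log2 intensity from DMSO to ATRA (x axis) of each measured gene of 12 of the 30 gene lists (y axis), each point a gene, filled points those past the threshold and vertical bars the medians. Of the 20 retinoic acid responsive genes 18 lie above 0, while the housekeeping genes centre on a median of -0.025.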

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

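The robust eBayes and the list without Cyp26a1 and Cdx1 were chosen after seeing the data. A called gene could hardly reverse when an array was left out, since both ATRA arrays lay beyond both DMSO arrays on all 302 called probes. The filter, the eBayes settings and the block do not alter the change itself, so a kept direction is weak evidence. Of the 41 named genes past the threshold, each kept its direction under every alternative that gave it a value, and none of them reversed; of the genes not past it, Actb changed sign with the mean of all probes and Pou5f1 without DMSO replicate 1, past the threshold in neither. Of 642 gene results, 574 kept their side of the threshold, 66 lost their call and 2 gained one, the latter Rarb with no background correction (adjusted p = 0.042) and Zscan4c without DMSO replicate 2. The fit without the intensity trend in eBayes called 74 probes (70 rose, 4 fell) and 46 genes, all 46 among the 186 of the main result, and 16 of the 41 named genes. The cause was not tested. Leaving out each array in turn, with 1 array then assumed to vary like the other group, gave 133 to 956 probes, 114 to 592 rises, 19 to 364 falls and 83 to 545 genes; the 545 genes without DMSO replicate 2 held 180 of the 186. The replicate block called 492 probes, 153 of them falls, and 300 genes, including all 186. The deviations of same-numbered arrays had a correlation of -0.003 across probes, so the numbers were not taken to pair the arrays. Background correction, median centring, the offset, the series matrix values and the robust eBayes left the number of genes at 183 to 199 (Cyp26a1 was at 0.79 with no background correction and 1.26 with an offset of 50 in place of 1.99, and Otx2 at -1.29 in place of -1.83 with no background correction), and no filter on dim probes gave 153, with more probes adjusted for. With no filter Zbtb46, Evx1, Rnd3, Gata6, Klf5 and Wnt8a missed the threshold (adjusted p = 0.068 to 0.11). The stricter detection filter called 173 genes and left 9 of the 41 named genes untested, Cyp26a1 among them. The mean of all probes ended the calls of Sox2, Tgif1, Gadd45b, Klf5 and Bcl2l11. Camera called 1 list in the main result, 0 with an estimated correlation, 2 with no filter, 3 with the stricter filter, 4 with the replicate block and 2 to 4 without an array; fry called 3, and its mixed form, which allows change in either direction, 17 of 28. The retinoic acid responsive list was past the threshold under each alternative (adjusted p = 1.4e-10 to 0.045) except with an estimated correlation (adjusted p = 0.61). It also passed without Cyp26a1 and Cdx1 (camera adjusted p = 0.00022). The robust eBayes does not enter the list tests, so it was no test of this list. The correlation estimated for the list was -0.05, below the preset 0.01, so a higher correlation does not account for the 0.61. In that form the simulated raised list was missed too. Under the block the primed epiblast, streak and retinoid metabolism lists also passed (adjusted p = 0.00069, 0.041 and 0.043), and with the stricter filter the primed epiblast and the LIF and STAT3 lists (0.0010 and 0.0054). The primed epiblast list was not tested without Otx2, nor the metabolism list without Cyp26a1, so these calls may rest on those genes. The chip as a block was not run because the files name no chips. Signal over background limited what was seen: 40.1% to 42.3% of probes were detected on an array.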

Other observations

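The genes in this paragraph lie outside the naming rule and were chosen after their values were seen. Icam1, an adhesion molecule, rose 1.75-fold (limma adjusted p = 3.5e-06), the receptor gene Notch4 1.73-fold (adjusted p = 1.2e-05), the sphingosine phosphate receptor gene S1pr2 1.59-fold (adjusted p = 2.0e-05) and the stem cell factor receptor gene Kit 1.51-fold (adjusted p = 9.7e-05). The angiogenic factor gene Vegfa rose 1.76-fold (adjusted p = 7.3e-05) and Hbegf, an EGF receptor ligand, 1.53-fold (adjusted p = 0.0012). Elf3, a transcription factor of epithelia, rose 1.77-fold (adjusted p = 8.9e-06), the forkhead gene Foxn4 2.15-fold (adjusted p = 5.7e-06) and Snai1, a repressor of E-cadherin, 2.04-fold (adjusted p = 0.00035). The survival gene Mcl1 rose 1.59-fold (adjusted p = 4.1e-05) and Eras, a RAS gene of embryonic stem cells, 1.45-fold (adjusted p = 0.00032). These 11 genes passed with any array left out, while Kit, Hbegf, Snai1, Mcl1 and Eras missed the threshold with eBayes without the intensity trend (adjusted p = 0.073, 0.097, 0.096, 0.091 and 0.094). Another probe of Kit, Notch4, Vegfa and Elf3 missed the threshold (adjusted p = 0.081, 0.36, 0.29 and 0.055), while another probe of Elf3 and that of S1pr2 passed.

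Falls outside the naming rule, also chosen after their values were seen, included the zinc finger genes Sall1 and Sall3, which fell by 0.39 and 0.43 on the log2 scale (adjusted p = 0.024 and 0.025). Zfp296, a zinc finger gene of pluripotent cells, fell by 0.45 (adjusted p = 0.0041), with its other probe at -0.57 and also past the threshold. The WNT ligand gene Wnt5a fell by 0.48 (adjusted p = 0.025) and the WNT antagonist gene Sfrp1 fell by 0.37 (adjusted p = 0.033). The other probes of Sall1, Sall3, Wnt5a and Sfrp1 were lower too but missed the threshold (adjusted p = 0.052, 0.058, 0.53 and 0.20). Without ATRA replicate 1 Sall1, Sall3, Wnt5a and Sfrp1 missed the threshold (adjusted p = 0.33, 0.31, 0.18 and 0.13), and without ATRA replicate 2 all 5 genes did (Sall1 0.22, Sall3 0.13, Zfp296 0.16, Wnt5a 0.28, Sfrp1 0.50). Sall3 and Sfrp1 missed it without DMSO replicate 1 too (adjusted p = 0.086 and 0.073), and without the intensity trend all 5 genes did (Sall1 0.20, Sall3 0.21, Zfp296 0.16, Wnt5a 0.14, Sfrp1 0.27).

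Some rises rested on a low value of DMSO replicate 1. Probe ILMN_2866327, unnamed here, had the second largest rise of any probe, 1.88 on the log2 scale (SE 0.47, adjusted p = 0.039), with values of 4.17 and 7.31 on the DMSO arrays and 7.60 and 7.63 on the ATRA arrays. A probe of Asb6 and the brightest probe of Cox6b2 had rises of 0.99 and 0.92 (adjusted p = 0.031 and 0.024), with DMSO SDs of 0.96 and 0.92. That of Asb6 was not its brightest probe, which did not pass. These and ILMN_2866327 were the 3 probes past the threshold with an SD over 0.5 in a group. Without DMSO replicate 1 their changes were 0.31, 0.31 and 0.26 (adjusted p = 0.13, 0.30 and 0.19). Among called genes with other kept probes (90 genes), 118 of 124 other probes changed in the same direction in value (95.2%). Of these, 40 also passed. The exceptions in direction were probes of Eif5, Purb, Trim2, Ankrd10, Ddx19b and Sec22c. For genes not called the share was 60.2%, counted over the 2 brightest probes of each gene only. It was not matched on the size of the change, so it is no like reference.

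All tests that follow were written before their results were seen. The interval given for bright probes and its limits were added afterwards. The reading of the centring and handling tests as undecided was reached after their values were known. More probes rose than fell among those past the threshold (79.5% of 302), while the 2211 probes at an unadjusted p under 0.05 held 1198 rises and 1013 falls. Among the 118 called probes with a mean log2 intensity of 8 or more, 77.1% rose, where 60% or less had been set for dim probes hiding falls. The Wilson 95% interval of 68.8 to 83.8 treats probes as independent, although they share 4 arrays and some belong to 1 gene. The share passed the higher bound set against that cause, but the interval did not clear that bound. This share was not counted with an array left out. For these called probes it argues against that cause without excluding it. Centring of the arrays stays open: the share was 78.6% with median centring and the housekeeping median was near 0, but the deposited values were already quantile normalized, so the test could not undo it, which the bound set in advance had left out of account. A single array as the source also stays open, with 61.9% rises without DMSO replicate 2, 68.1% without DMSO replicate 1, 85.7% without ATRA replicate 1 and 78.9% without ATRA replicate 2. The 4 arrays allow 3 splits into pairs, too few for a share under 0.05. Of the 3, 1 gave as many probes (302), the real one. The highest other gave 0, with 2211 against 493 at an unadjusted limma p under 0.05. Each other split set 1 DMSO and 1 ATRA array in both groups, so a treatment difference widened the spread within groups. Their low counts are therefore no reference for the real split, and the comparison decides nothing.

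Dusp5, Gadd45b and Ddit3 rose, but 2 of 17 immediate-early, 1 of 16 FGF and ERK feedback and 1 of 23 heat shock and unfolded protein genes passed and none of these lists was called by camera (adjusted p = 0.35, 0.62 and 0.35), while fry's mixed test for change in either direction gave 0.0083, 0.015 and 0.034; without DMSO replicate 2 the FGF and heat shock counts were 2 and 3, and without ATRA replicate 1 the heat shock count was 0. Handling of the cells may raise single genes of this kind. In each of the lists named above the share that passed, of 1 or 2 genes, was larger than over all measured genes (186 of 10194). The serum-inducible genes Dusp1, Egr1, Fos, Jun, Zfp36 and Junb, the 6 of 11 that were kept, had a median change of 0.03, with values from -0.16 to 0.20 and 0 past the threshold. A median of 0.1 or less had been set to count against handling, but the members went both ways, and genes of this kind can peak and return before 2 hours, so the median decides nothing and these rises cannot be told apart from handling. A response to ATRA remains open, as untested beyond the comparison itself.

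Called genes beside each other in the genome were counted as a hypothesis of shared local regulation. Among 10181 ordered genes there were 3 pairs of neighbours called in the same direction, Zfhx2 with Thtpa, Thtpa with Ap1g2, and Ier5l with Ntmt1, all higher. Random sets of 186 genes matched on intensity had a median of 2 pairs and a 95th percentile of 5 (permutation p = 0.41, 10000 sets). The data do not separate this count from random sets.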
